A study of Mus musculus with 12 samples.

How the data were processed

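RNA was measured in 12 libraries of mouse embryonic stem cells, 3 per group, in 4 groups: wild-type and Notch1-deficient cells at day 0 and as day 6 embryoid bodies. Per the labels, the cells were of C57BL/6J origin and were grown on mouse embryonic fibroblast feeders or on gelatin with LIF at 1000 U/ml; which of these applied to which library is not stated. Cardiac differentiation was started in hanging drops of 1000 cells, and embryoid bodies were collected on day 6. RNA was extracted with Trizol, selected for poly(A) and sequenced on an Illumina HiSeq2000 as pairs of reads of 100 bases, per the labels' protocols.

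The submitters' processing notes name TopHat2 2.0.8, Cufflinks 2.1.1, HTSeq 0.5.4p3 and DESeq with genome build mm9. The role and order of each tool, the strand setting of the counting and any filters are not given in the sources used here. The authors deposited raw counts per merged locus, FPKM values for the same loci, and the merged transcript models, whose exon starts and ends are 1-based mm9 coordinates. The deposited count columns are whole numbers that sum to between 100637179 and 134662426 per library. The deposited FPKM values are not whole and were normalised by the authors by transcript length and library size. The merged models held 40039 loci and 144343 transcripts. Of these loci, 12765 consist only of transcripts classed as intergenic by the deposited models.

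The files pair loci with transcript identifiers that occur in neither of the name tables available, so they give no gene symbols that could be read directly. Symbols came from the provided name table. Loci were linked to it through the structure of their transcripts, that is, by matching the lengths of consecutive exons and introns to those of annotated transcripts of a reference on another build, and no coordinates were converted. This linked 16413 loci to 1 gene each. Of them, 15258 were linked by at least 2 exon-intron links, or by 1 with an outer exon. Another 612 were linked by both outer exons, and 543 by a single link. Outer exons counted only next to an intron of at least 200 bases. A further 1420 loci merged several genes, 112 were matched in part and 22094 were not matched. As a check, the loci were also looked up on another chromosome, where these 3 rules gave 0, 0 and 3 false matches. The shift between builds lay within 1 Mb of the median of the 10 neighbouring matches for 99.948%, 100% and 100% of the real matches. A rule for genes with 2 exons gave 46 false matches in the check. Its matches were dropped for 628 loci after the first list results had been seen. Genes such as Hand1, Sox7, Mesp2, Cer1, Mixl1 and Nr0b1 are therefore missing from their lists. Gene names therefore rest on this inference and not on identifiers.

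Counts of loci that share exons with other loci are unreliable, because reads that touch more than 1 locus appear to be left out. Of all loci, 4677 shared at least 50% of their exon length with another, 2686 of them among the 23991 tested, and 494 had 0 counts in all 12 libraries with a mean FPKM of at least 1. Hes1, Bmp4 and Zic2 are examples, and for such genes FPKM is given and named as such. Antisense genes and their partners cannot be separated, since no strand setting is stated. Genes with near-identical copies, such as Nlrp genes and pseudogenes, may share reads, and their values are uncertain.

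The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling and edgeR's default filter for expressed loci, which left 23991 loci. All 12 libraries entered 1 fit with a mean per group, so that the groups share an estimate of the spread. The contrasts were day 6 against day 0 within each genotype, Notch1-deficient against wild type within each day, and the difference of the differences. Benjamini-Hochberg adjusted p-values under 0.05 were called, over all loci and, for the list members, over the list alone. The 10 most abundant loci took 4.74% to 6.77% of the counts in a library, and TMM factors ran from 0.908 to 1.14. At this depth counting error is small against the spread between libraries: the chi-square per degree of freedom between replicates was 41.3 to 404. Where a group had 0 counts, a bound of 3 counts over the group was used, which covers counting error only.

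Of 31 gene lists written before the data were examined, the 28 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. A list of feeder fibroblast markers was among them. The genes named were chosen by a rule that was also fixed before the data were examined. It took Notch1, the 8 higher and 8 lower called genes with the greatest change per contrast (a symbol that is no clone or pseudogene name, a mean log2 CPM of at least 2, and no overlap of replicate values outside the interaction), the up to 5 members of each list with the smallest p, the 3 higher and 3 lower noncoding genes per genotype contrast with a mean log2 CPM of at least 1, and the Notch and cardiac progenitor list members in the genotype contrasts. Not every gene it allows is named. Genes reported by FPKM, and the unannotated loci, were chosen after their values were seen.

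The tests were tried on simulated data with 22998 or 23005 genes. These used the real library sizes, the estimated spread of each locus and 1 mean per locus over all 12 libraries. Apart from the changes placed, the groups did not differ. With changes placed in the Notch1-deficient day 6 group, 17.5% of changes of 1 and 47.9% of changes of 2 on the log2 scale were recovered for the genotype at day 6, and the same shares for differentiation in Notch1-deficient cells, with 3 and 5 false calls. For the interaction the shares were 2.06% and 28.1%, with 1 false call. With changes placed in the wild-type day 0 group, they were 24.7% and 53.6% for the genotype at day 0 and 20.6% and 48.5% for differentiation in the wild type, with 7 false calls in each, and 4.12% and 24.7% for the interaction, with 6 false calls. All 4 changed gene sets were called in each of these contrasts, and 0 others. The genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.

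Alternatives were DESeq2 size factors and upper quartile scaling, no filter on low counts, a mean CPM of at least 1, DESeq2 (1.42.0), limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 (14133 loci), limma on unfiltered FPKM, fits of only the groups compared, a replicate block, leaving out each library, and for lists an estimated correlation and fry. Added after seeing the data were leaving out both day 0 libraries numbered 3, only loci with under 50% of exon length shared, and lists with the 2-exon matches added. A covariate of the feeder fibroblast level, in a fit of only the day 0 libraries, was also added then. For the genotype comparison at day 0, deviations from the group means of same-numbered libraries correlated at 0.46, 0.36 and 0.27 for numbers 1, 2 and 3. Whether these libraries were paired stays open. The labels do not say what a shared number means. The submitters' own sample names carry another numbering, under which wild-type day 0 library 3 would match Notch1-deficient day 0 library 2. In the other contrasts at least 1 same-numbered pair correlated below 0.1, which gives no ground for pairing those samples. Upper quartile scaling moved the median change of all loci from -0.122 to -0.286 for differentiation in the wild type and from -0.019 to -0.176 in Notch1-deficient cells.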

Results

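Poly(A) RNA was profiled in mouse embryonic stem cells of 2 genotypes, wild type and Notch1-deficient, before differentiation (day 0) and as embryoid bodies on day 6 of differentiation. Embryoid bodies are aggregates of stem cells in which early embryonic tissues form after the factor LIF is withdrawn. Each of the 4 groups held 3 libraries, 12 in all. The deposited table held from 100637179 to 134662426 counts per library over 40039 merged loci. The series asked which coding and noncoding transcripts change when Notch1, a receptor for cell-to-cell signalling, is missing. The series design speaks of 3 biological replicates per condition. The labels do not say whether these were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Expression is given as normalised read counts (CPM, counts relative to the TMM-scaled library size), as mean ± SD with n = 3 libraries per group. Fold changes are log2 values from edgeR with their standard errors (SE). Coordinates are those of mouse genome build mm9.

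The targeted gene was measured first. Notch1 (locus XLOC_020472, chromosome 2, 26301026 to 26363148, minus strand) had 61.6, 24.7 and 34.0 CPM in wild-type libraries 1, 2 and 3 at day 0, and 38.0, 30.9 and 31.1 CPM at day 6. In the Notch1-deficient libraries it had 3.80, 3.87 and 4.59 CPM at day 0, and 6.80, 4.90 and 4.95 CPM at day 6. All 6 Notch1-deficient libraries lay below all 6 wild-type libraries. The change in the deficient cells was -3.29 (SE 0.30) at day 0 and -2.58 (SE 0.30) at day 6 (adjusted p = 4.32e-05 and 7.29e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Residual counts remained at the locus, and 22.27% of its exon length was shared with other loci. Which part of the gene was deleted is not stated in the labels.

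**Figure D1:**
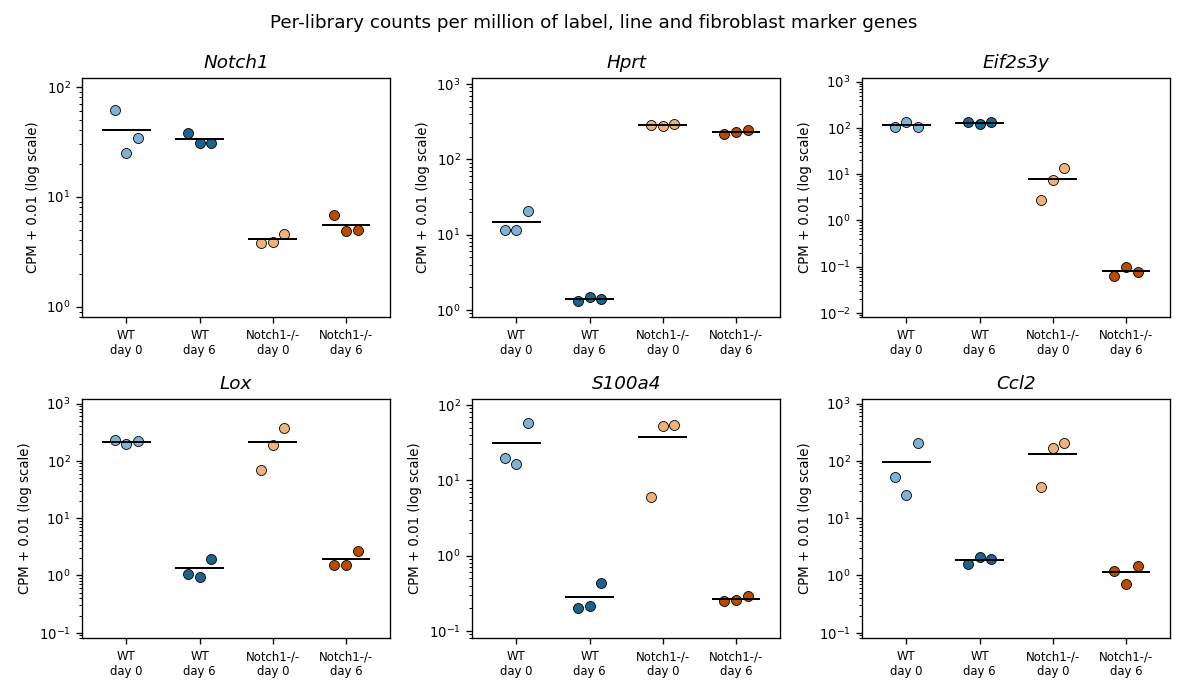
Expression in CPM (log scale, 0.01 added) of Notch1, Hprt, Eif2s3y, Lox, S100a4 and Ccl2 in the 4 groups; each point is 1 library and each line the mean of 3 libraries. Notch1 lies between 24.7 and 61.6 CPM in the wild type and at or below 6.80 CPM in the Notch1-deficient libraries, whereas Lox, S100a4 and Ccl2 are high in the day 0 groups of both genotypes.

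The first comparison asked what 6 days of differentiation changed in wild-type cells. Genes of cardiac progenitors and of vessel and yolk sac lineages rose and genes of pluripotency fell. Genes of the germline and of fibroblasts fell too, but these lists were not called with an estimated correlation (adjusted p = 0.185 and 0.575, camera), and the fibroblast list was not called without wild-type day 0 library 3 (0.0647). Tbx20, a T-box factor of the early heart, rose from 1.63 ± 0.43 to 265 ± 70.3 CPM. Ttr, a carrier protein of visceral endoderm and liver, rose from 0.0475 ± 0.0338 to 51.6 ± 8.16 CPM. Zfp42, also known as Rex1 and a marker of naive stem cells, fell from 769 ± 205 to 111 ± 15.9 CPM. Lox, which cross-links collagen in connective tissue, fell from 217 ± 20.7 to 1.32 ± 0.567 CPM. Notch1 itself was not called (-0.27, SE 0.28; 0.18 without library 1 of day 0, -0.51 without library 2 of day 0 and -0.42 under upper quartile scaling).

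In all, 4404 loci rose and 5910 fell among the 23991 tested (edgeR's quasi-likelihood test, adjusted p under 0.05), and 7838 of these changed at least 2-fold. Higher loci were 42.7% of the calls, and 32.9% under upper quartile scaling. Among the called genes with a mean log2 CPM of at least 2, Prdm6 (10.08, SE 1.23), a repressor of smooth muscle genes, and Capn6 (8.27, SE 0.76), a calpain-like protein of the embryo, rose. Pitx1 (7.29, SE 0.42), a homeobox factor of the hindlimb, Rgs5 (6.98, SE 0.75), a pericyte gene, and Igfbp5 (6.84, SE 0.64) also rose. Unc5c, a netrin receptor, rose by 7.32 (SE 0.62). Igf2, an imprinted growth factor, rose from 106 ± 9.62 to 11200 ± 685 CPM (6.72, SE 0.48). For Igf2 the deposited FPKM values disagree with the counts, since FPKM is listed at 0 in all 3 wild-type day 6 libraries against 17.7 at day 0. Inhba (-8.16, SE 0.90), a subunit of activin, fell, as did matrix genes such as Mgp (-6.75, SE 1.09), Ltbp2 (-6.31, SE 0.48), Bgn (-6.25, SE 0.58) and Thbs2 (-6.06, SE 0.71). Inhba varied widely at day 0 (488 ± 353 CPM). Feeder RNA present at day 0 and lost by day 6 may contribute to falls such as these, which was not tested. Slc27a2, a fatty acid transporter, fell by 5.71 (SE 0.61). The noncoding RNAs Rubie (8.86, SE 0.95) and Fendrr (6.06, SE 0.54), the latter needed in lateral mesoderm, rose.

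Gene groups were read through lists fixed before the data were examined, tested with camera and adjusted over 28 lists. Of 17 tested members of the naive pluripotency list, 0 rose and 14 fell over all genes, and 14 fell adjusted over the list alone (median -1.67, camera adjusted p = 8.09e-11, and adjusted p = 0.0388 with an estimated correlation). Zfp42 (-2.79, SE 0.24), Klf5 (-2.79, SE 0.19), Esrrb (-2.32, SE 0.25) and Fbxo15 (-2.32, SE 0.21) were among them. Of 18 cardiac progenitor genes 14 rose, 0 fell and 4 were not called, with the same counts adjusted over the list alone (median 3.26, camera adjusted p = 3.88e-12, and adjusted p = 0.0462 with an estimated correlation). Kdr (6.16, SE 0.59), a receptor of mesoderm and endothelium, Isl1 (5.31, SE 0.48), Gata6 (5.26, SE 0.44) and Bmp2 (4.59, SE 0.37) rose. Of 21 endothelial and blood genes 18 rose and 1 fell, with the same counts adjusted over the list alone (median 3.87, camera adjusted p = 5.24e-13, and adjusted p = 0.0409 with an estimated correlation). They included the endothelial cadherin Cdh5 (7.59, SE 0.43) and the blood and vessel regulators Fli1 (6.06, SE 0.54) and Tal1 (4.72, SE 0.56). Of 23 extraembryonic endoderm genes 18 rose and 1 fell, again with the same counts adjusted over the list alone (median 2.42, camera adjusted p = 5.24e-13, and adjusted p = 0.0388 with an estimated correlation). Besides Ttr (10.04, SE 0.72), the lipid carrier gene Apob (5.69, SE 0.37) and the retinol carrier gene Rbp4 (3.96, SE 0.34) rose.

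Imprinted genes rose as a group in the wild type: 17 of 20 rose and 1 fell, against 17 and 2 adjusted over the list alone (median 2.46, camera adjusted p = 5.25e-13, and adjusted p = 0.0104 with an estimated correlation). Peg3 went from 127 ± 60.9 to 3200 ± 357 CPM and Dlk1, a Notch ligand-like protein, rose by 5.81 (SE 0.63). Primitive streak genes gave 7 rises and 2 falls of 10, with the same counts adjusted over the list alone (median 2.75, camera adjusted p = 0.00327, but adjusted p = 0.174 with an estimated correlation). Foxa2 (5.22, SE 0.66) and Rspo3 (4.48, SE 0.48) rose. Over only the loci with under 50% of their exon length shared, the streak list gave an adjusted p = 0.0513 (camera). Wnt target genes gave 9 rises and 3 falls of 14, against 9 and 4 adjusted over the list alone (median 1.15, camera adjusted p = 0.00146, but adjusted p = 0.147 with an estimated correlation), led by Nkd1 (4.47, SE 0.39) and Axin2 (2.21, SE 0.33), both feedback inhibitors of the pathway. Neural crest genes gave 6 rises and 1 fall of 11, also adjusted over the list alone (median 1.75, camera adjusted p = 0.01, but adjusted p = 0.192 with an estimated correlation). The endothelin receptor gene Ednrb rose by 5.70 (SE 0.41). Definitive endoderm genes gave 6 rises and 1 fall of 9, also adjusted over the list alone (camera adjusted p = 0.00767, but adjusted p = 0.192 with an estimated correlation); their median was 1.34, and 3.04 without wild-type day 0 library 2. Germline and 2-cell-stage genes gave 0 rises and 14 falls of 16, also adjusted over the list alone (median -2.40, camera adjusted p = 1.85e-05, but adjusted p = 0.185 with an estimated correlation). Dmrt1 (-2.64, SE 0.39) and Mael (-2.35, SE 0.34), a piRNA pathway gene, fell.

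Fibroblast markers moved with the day in both genotypes. Of 23 feeder fibroblast genes 2 rose and 12 fell in the wild type, against 3 and 12 adjusted over the list alone (median -1.73, camera adjusted p = 0.0079, but adjusted p = 0.575 with an estimated correlation). This call was lost without wild-type day 0 library 3 (median -0.96, camera adjusted p = 0.0647). S100a4, a fibroblast calcium-binding protein, fell by 6.82 (SE 0.85) and the chemokine gene Ccl2 fell by 5.67 (SE 0.83). The mean log2 CPM of the list was 5.74, 4.93 and 6.83 in wild-type day 0 libraries 1, 2 and 3, and 3.88, 3.95 and 4.04 at day 6. Mesenchymal genes rose in spite of this, 8 up and 1 down of 13, also adjusted over the list alone (median 1.24, camera adjusted p = 0.000282, but adjusted p = 0.351 with an estimated correlation), and Tgfb2, a growth factor of the TGF-beta family, rose by 5.18 (SE 0.37). Notch target genes gave 7 rises and 5 falls of 16, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.0617). Hey2 (4.65, SE 0.41) and Hey1 (2.02, SE 0.32), transcription factors induced by Notch, rose while Rbpj, the DNA-binding partner of the receptors, fell by 1.52 (SE 0.22). The cardiomyocyte sarcomere list was evenly divided, 7 up and 7 down of 19, against 7 and 8 adjusted over the list alone (median 0.00, camera adjusted p = 0.832), and Tnni1, an embryonic troponin, rose by 4.37 (SE 0.49).

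**Figure D2:**
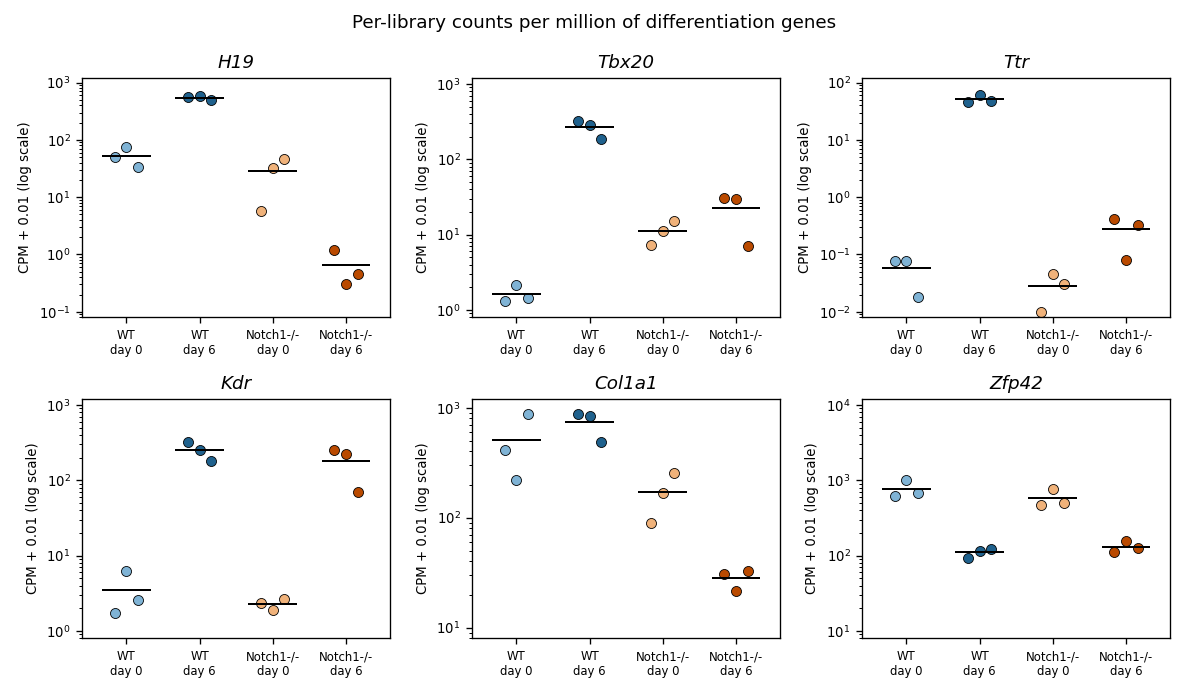
Expression in CPM (log scale, 0.01 added) of H19, Tbx20, Ttr, Kdr, Col1a1 and Zfp42 in the 4 groups; each point is 1 library and each line the mean of 3 libraries. Kdr reaches 251 CPM in wild-type and 182 CPM in Notch1-deficient embryoid bodies, while H19 reaches 543 CPM in the former and 0.638 CPM in the latter.

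The second comparison asked the same of Notch1-deficient cells. Pluripotency genes fell here as well, and genes of the primitive streak and of Wnt signalling rose, but none of the 3 lists was called with an estimated correlation (adjusted p = 0.0533, 0.0533 and 0.0765, camera). Zfp42 fell from 581 ± 163 to 132 ± 21.3 CPM and Kdr rose from 2.3 ± 0.366 to 182 ± 98.8 CPM. Wnt8a, a Wnt ligand of the streak, rose from 2.24 ± 1.24 to 88.2 ± 3.51 CPM. H19, an imprinted noncoding RNA, fell from 28 ± 20.5 to 0.638 ± 0.467 CPM. In Notch1-deficient day 0 libraries 1, 2 and 3 H19 had 5.64, 32.6 and 45.8 CPM. It rose there with the feeder list (mean log2 CPM of 4.33, 5.39 and 5.99). In wild-type day 0 libraries 1, 2 and 3, with 50.7, 74.7 and 33.5 CPM, it did not. Feeder RNA lost by day 6 may explain the fall in deficient cells, which was not tested. Notch1 was not called (0.44, SE 0.28, and 0.28 without library 1 of day 6 or under upper quartile scaling), and by FPKM its change was -0.07 (FPKM + 1) or -0.22 (FPKM + 0.1).

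There were 4093 loci that rose and 4468 that fell (edgeR's quasi-likelihood test, adjusted p under 0.05), of which 6446 changed at least 2-fold. Higher loci were 47.8% of the calls, and 37.0% under upper quartile scaling. The secreted Wnt inhibitor Frzb (6.82, SE 0.62), Lzts1 (6.76, SE 0.68), Wnt3 (5.60, SE 0.59), Greb1 (4.81, SE 0.73) and Vrtn (4.77, SE 0.37) rose. So did Evx1os (5.33, SE 0.79), whose locus is antisense to Evx1 and shares 51.04% of its exon length, so that its reads and those of Evx1 cannot be separated. Inhba (-9.51, SE 0.95), the interleukin receptor gene Il1rl1 (-9.20, SE 0.98), Fgf7 (-8.36, SE 0.67), Ccl7 (-7.92, SE 1.01), the collagenase gene Mmp13 (-6.91, SE 0.82), Ccl2 (-6.90, SE 0.88) and Lox (-6.79, SE 0.59) fell. Here too, Inhba varied widely at day 0 (1200 ± 925 CPM). Feeder RNA lost by day 6 may contribute to these falls, which was not tested. Rubie rose by 6.16 (SE 0.83).

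Naive pluripotency genes gave 0 rises and 15 falls of 17, also adjusted over the list alone (median -1.54, camera adjusted p = 3.18e-11, but adjusted p = 0.0533 with an estimated correlation), among them Fbxo15 (-2.49, SE 0.21), Klf5 (-2.28, SE 0.18) and Zfp42 (-2.14, SE 0.23). Primitive streak genes gave 9 rises and 0 falls of 10, and 10 rises adjusted over the list alone (median 2.81, camera adjusted p = 3.29e-08, but adjusted p = 0.0533 with an estimated correlation). Foxa2 (5.23, SE 0.66) and Rspo3 (2.95, SE 0.45) rose. Primed epiblast genes gave 6 rises and 0 falls of 7, also adjusted over the list alone (median 1.22, camera adjusted p = 0.0151, but adjusted p = 0.321 with an estimated correlation), and Fgf5, a marker of the post-implantation epiblast, rose by 3.99 (SE 0.55). Wnt targets gave 8 rises and 1 fall of 14, against 10 and 2 adjusted over the list alone (median 1.57, camera adjusted p = 3.6e-05, but adjusted p = 0.0765 with an estimated correlation), with Nkd1 (4.38, SE 0.39) and Axin2 (3.42, SE 0.35). Cardiac progenitor genes gave 7 rises and 1 fall of 18, also adjusted over the list alone (median 0.90, camera adjusted p = 0.00179, but adjusted p = 0.321 with an estimated correlation). Gata6 (4.11, SE 0.42) and Isl1 (3.02, SE 0.44) rose. Germline and 2-cell-stage genes gave 0 rises and 12 falls of 16, against 13 falls adjusted over the list alone (median -2.70, camera adjusted p = 1.96e-06, but adjusted p = 0.27 with an estimated correlation), and Mael fell by 2.68 (SE 0.34).

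The extraembryonic endoderm, endothelial and blood, and imprinted lists, which rose in the wild type, were not called here. Extraembryonic endoderm genes gave 7 rises and 5 falls of 23, against 8 and 7 adjusted over the list alone (median 0.33, camera adjusted p = 0.943). Endothelial and blood genes gave 7 and 3 of 21, also adjusted over the list alone (median 0.08, camera adjusted p = 0.391). Imprinted genes gave 7 and 3 of 20, also adjusted over the list alone (median 0.30, camera adjusted p = 0.375), with Peg3 up by 3.16 (SE 0.41) and H19 at -5.47 (SE 0.72). The differences between genotypes in these lists were tested as an interaction. Of the feeder fibroblast genes 0 rose and 20 of 23 fell, against 21 adjusted over the list alone (median -3.47, camera adjusted p = 5.56e-12, but adjusted p = 0.294 with an estimated correlation). The mean log2 CPM of that list was 4.33, 5.39 and 5.99 in Notch1-deficient day 0 libraries 1, 2 and 3, and 1.67, 1.61 and 2.06 at day 6. S100a4 (-7.18, SE 0.86), the limb and craniofacial mesenchyme factor Prrx1 (-6.14, SE 0.61) and the matrix protein gene Postn (-4.97, SE 0.61) fell. Of the 6 genes of the sex chromosome list 5 fell, also adjusted over the list alone (median -6.48, camera adjusted p = 1.79e-08, but adjusted p = 0.0533 with an estimated correlation), and Eif2s3y went from 7.95 ± 5.47 to 0.069 ± 0.016 CPM. Ddx3y fell by 6.76 (SE 0.61). In Notch1-deficient day 0 libraries 1, 2 and 3 the Y-linked genes rose with the feeder list, with 2.69, 7.56 and 13.6 CPM for Eif2s3y, 3.17, 9.83 and 17.6 CPM for Ddx3y, and 1.00, 1.95 and 3.29 CPM for Uty. In the Notch pathway the ligand genes Dll1 (2.77, SE 0.59) and Jag1 (0.95, SE 0.17) and the target Hey1 (1.77, SE 0.32) rose, and Rbpj fell by 1.66 (SE 0.23).

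Across the 23991 loci the differentiation changes of both genotypes had a Pearson correlation of 0.626, a value across genes, which are not independent replicates. There were 2147 loci higher at day 6 in both genotypes (751.3 if the calls were independent), 2900 lower in both (1100.7 if independent) and 366 called in opposite directions.

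The third comparison set Notch1-deficient against wild-type cells at day 0. No developmental gene list was called, and the greatest differences among the named genes lay in the Y-linked genes, Hprt and single genes of unlike function. Hprt, the X-linked purine salvage enzyme gene (chromosome X, 50341255 to 50374958), had 14.6 ± 5.28 CPM in the wild type and 284 ± 9.02 CPM in the deficient cells. Eif2s3y, a Y-linked translation factor gene, had 116 ± 15.9 and 7.95 ± 5.47 CPM. Mirg, a noncoding RNA of the imprinted Dlk1 region on chromosome 12, had 63.6 ± 20.8 and 2.97 ± 1.45 CPM.

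At day 0, 873 loci were higher and 1373 lower in Notch1-deficient cells (edgeR's quasi-likelihood test, adjusted p under 0.05), and 1844 differed at least 2-fold. Klhdc4 (5.01, SE 0.27), a kelch-domain protein gene, Hprt (4.28, SE 0.22), Ankrd31 (4.18, SE 0.29), a meiosis gene, Dnaaf1 (3.76, SE 0.50), a factor of dynein arm assembly, Aox4 (3.29, SE 0.28), Nlrp4f (3.17, SE 0.43), Prg4 (3.07, SE 0.51) and Pttg1 (2.96, SE 0.27), which encodes securin, were higher. Klhdc4 shares 34.08% of its exon length with other loci, and its FPKM rose less, from 18.4 to 42.0. Prg4 lost its call on unfiltered FPKM (adjusted p = 0.0558, limma). Besides Mirg (-4.42, SE 0.38), Uty (-4.39, SE 0.42), Eif2s3y (-3.86, SE 0.43) and Ddx3y (-2.85, SE 0.47), Crocc2 (-3.50, SE 0.40) and Slc6a16 (-3.24, SE 0.34) were lower. AI506816 was lower by counts (-2.73, SE 0.38), and by FPKM its change was not called (-0.94 on FPKM + 1, adjusted p = 0.539, and -1.99 on FPKM + 0.1, adjusted p = 0.471, limma), with 62.66% of its exon length shared. The noncoding RNA Gm33301 was higher (6.21, SE 0.39) and the pseudogene Gm18562 lower (-3.10, SE 0.42); reads of a pseudogene may belong to its parent gene. The unannotated intergenic locus XLOC_009067 (chromosome 13, 19608914 to 19620273) had 30041 counts over the 3 wild-type day 0 libraries and 2 in the deficient ones.

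At day 0 camera called 2 of 28 lists. Of the 6 sex chromosome genes 0 were higher and 3 lower, also adjusted over the list alone (median -1.73, camera adjusted p = 1.65e-05, but adjusted p = 0.213 with an estimated correlation). The Y-linked Kdm5d was not called (3.25 ± 1.40 and 2.63 ± 1.52 CPM). In libraries 1, 2 and 3 it had 2.985, 2.00 and 4.77 CPM in the wild type and 1.14, 2.56 and 4.18 CPM in deficient cells. Within each genotype this is the order of the feeder list means. At day 6 Kdm5d had 0.0617 CPM in wild-type and 0.0303 CPM in deficient libraries. The like day 0 values may therefore come from feeder RNA, which was not tested. In Notch1-deficient day 6 libraries Uty, Eif2s3y and Ddx3y had at most 16 counts each, so few reads of related genes were counted at these loci. Ribosomal protein genes were shifted up with 1 of 23 called higher, and 0 adjusted over the list alone (median 0.23, camera adjusted p = 0.0233, but adjusted p = 0.802 with an estimated correlation). That shift was not called without wild-type day 0 library 1 (adjusted p = 0.139), library 3 (0.308) or Notch1-deficient library 1 (0.109), all by camera, and its median was 0.44 without wild-type library 2. The count of called lists was 1 without wild-type library 1 or 3, and 4 without wild-type library 2 or Notch1-deficient library 3.

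Developmental lists were not called at day 0. Naive pluripotency genes gave 3 higher and 0 lower of 17, also adjusted over the list alone (median 0.07, camera adjusted p = 0.329), the 3 including Dppa3 (2.07, SE 0.29), a maternal factor with 47.48% of its exon length shared. Germline and 2-cell-stage genes went both ways, 7 higher and 4 lower of 16, against 7 and 5 adjusted over the list alone (median 0.40, camera adjusted p = 0.497; their mean was below 0). Cardiac progenitor genes gave 1 higher and 0 lower of 18, against 2 and 1 adjusted over the list alone (median -0.01, camera adjusted p = 0.643, with a test direction of higher). Of 16 Notch targets 0 were higher and 1 lower, also adjusted over the list alone (median -0.35, camera adjusted p = 0.614). This was Jag1 (-0.77, SE 0.17), a ligand that Notch can itself induce, whose call was lost without Notch1-deficient day 0 library 3 (adjusted p = 0.0596, edgeR's quasi-likelihood test). Of 23 Notch pathway components 0 were higher and 2 lower, also adjusted over the list alone (median 0.03, camera adjusted p = 0.674, with a test direction of lower). Pmaip1, a proapoptotic p53 target, was higher (1.78, SE 0.20). Of the 23 feeder fibroblast genes 0 were called at day 0 in edgeR, also adjusted over the list alone (median -0.94, camera adjusted p = 0.329), although their mean log2 CPM varied from 4.33 to 6.83 among these 6 libraries.

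The day 0 count depended on single libraries: it was 1246 without wild-type library 1, 5964 without wild-type library 2, 4152 without Notch1-deficient library 1, 1095 without Notch1-deficient library 2 and 1480 without Notch1-deficient library 3. It was 962 without both libraries numbered 3, which had the highest fibroblast marker levels of their groups. It was 449 in a fit of only the day 0 libraries with the mean level of the feeder fibroblast list as a covariate. The count already fell when only the day 0 libraries were fitted without the covariate, so the fall to 449 is not due to the covariate alone.

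The fourth comparison set both genotypes side by side as embryoid bodies. Genes of yolk sac endoderm and of vessels and blood were lower in Notch1-deficient embryoid bodies, and genes of the neural lineage were higher. Lists of mesenchyme and the early heart were lower and lists of the epiblast, the primitive streak and the cell cycle higher with the preset correlation, but none of these 5 was called with an estimated one (adjusted p = 0.222, 0.114, 0.152, 0.227 and 0.222, camera). H19 had 543 ± 47 CPM in the wild type and 0.638 ± 0.467 CPM in the deficient embryoid bodies, and Pitx1 137 ± 36.4 and 0.395 ± 0.211 CPM. Cdh5 had 49.5 ± 10.1 and 1.25 ± 0.376 CPM. Fgf5 was higher, with 9.61 ± 5.57 and 144 ± 26.4 CPM. Kdr, a marker of cardiac and vascular progenitors, was not called, with 251 ± 70.3 and 182 ± 98.8 CPM.

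At day 6, 3269 loci were higher and 3443 lower in Notch1-deficient embryoid bodies (edgeR's quasi-likelihood test, adjusted p under 0.05), and 4835 differed at least 2-fold. Klhdc4 (8.29, SE 0.31), Hprt (7.38, SE 0.25) and Ankrd31 (6.59, SE 0.32) were again higher. By FPKM the change of Klhdc4 was much smaller (2.75 on FPKM + 1, from 11.1 to 80.1 FPKM). Slc27a2 (4.92, SE 0.59), Pianp (4.76, SE 0.37), the noncoding RNA Miat (4.37, SE 0.62), Fam25c (4.29, SE 0.38) and Wnt8a (4.28, SE 0.41) were also higher. H19 (-9.75, SE 0.85), Mirg (-8.76, SE 0.47), Pitx1 (-8.44, SE 0.45), Postn (-7.15, SE 0.67), Hapln1 (-6.53, SE 0.68), a cartilage link protein, Acta2 (-6.44, SE 0.55), smooth muscle actin, Tbx4 (-6.38, SE 0.49), a factor of hindlimb and allantois, and Col3a1 (-5.78, SE 0.77) were lower. The unannotated locus XLOC_001616 on chromosome 1 was higher (8.83, SE 0.41).

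**Figure D3:**
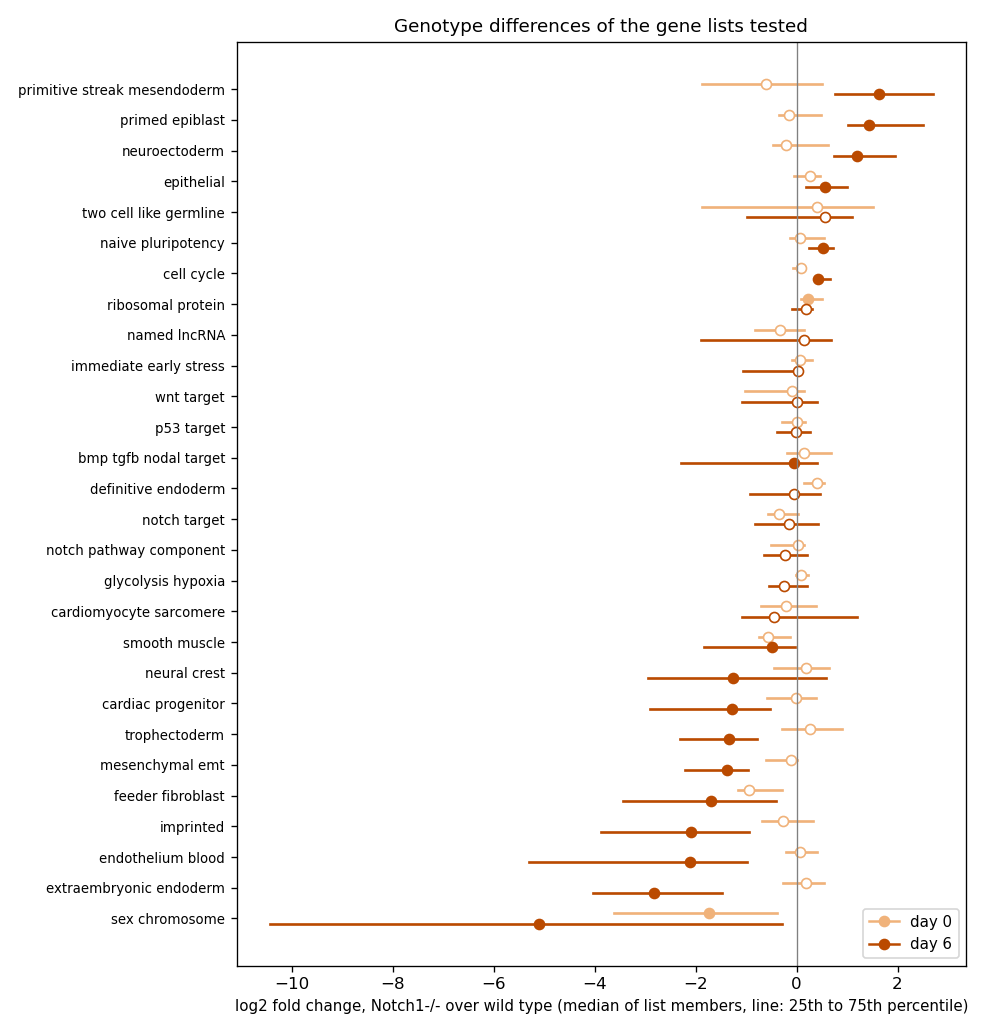
Median log2 fold change of Notch1-deficient over wild-type libraries for each gene list (points, light for day 0 and dark for day 6), with lines from the 25th to the 75th percentile of the members; filled points had a camera adjusted p under 0.05. The extraembryonic endoderm list lies at -2.83 and the primed epiblast list at 1.43 on day 6, and 2 lists are filled at day 0 against 17 at day 6.

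Of 23 extraembryonic endoderm genes 1 was higher and 20 lower, also adjusted over the list alone (median -2.83, camera adjusted p = 3.82e-18, and adjusted p = 0.00431 with an estimated correlation). Ttr (-7.59, SE 0.62), Apob (-3.95, SE 0.34) and Rbp4 (-3.71, SE 0.34) were lower. Of 20 imprinted genes 14 were lower and 0 higher, also adjusted over the list alone (median -2.10, camera adjusted p = 5.8e-16, and adjusted p = 0.00431 with an estimated correlation). Dlk1 (-5.42, SE 0.62) was lower, and Igf2 by counts (-5.71, SE 0.46) while by FPKM the direction was reversed, since the wild-type day 6 values are listed at 0. Of 21 endothelial and blood genes 17 were lower and 0 higher, against 18 adjusted over the list alone (median -2.12, camera adjusted p = 3.11e-14, and adjusted p = 0.0287 with an estimated correlation). The vascular factor Erg (-5.58, SE 0.46), Cdh5 (-5.31, SE 0.38) and Tal1 (-4.58, SE 0.55) were lower. Of the 6 sex chromosome genes 3 were lower, also adjusted over the list alone (median -5.11, camera adjusted p = 4.86e-09, and adjusted p = 0.0287 with an estimated correlation), namely Uty (-11.07, SE 0.62), Eif2s3y (-10.85, SE 0.62) and Ddx3y (-9.20, SE 0.66). Of 13 neuroectoderm genes 6 were higher and 1 lower, against 8 and 1 adjusted over the list alone (median 1.19, camera adjusted p = 0.000155, and adjusted p = 0.0287 with an estimated correlation), with the forebrain factor Otx1 (3.40, SE 0.47) and the microtubule protein gene Map2 (1.95, SE 0.32).

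Further lists were called with the preset correlation but not with an estimated one. Cardiac progenitor genes gave 9 lower and 0 higher of 18, also adjusted over the list alone (median -1.28, camera adjusted p = 1.49e-06, but adjusted p = 0.114 with an estimated correlation). Tbx20 (-3.56, SE 0.49), Isl1 (-3.34, SE 0.43), Mef2c (-3.01, SE 0.29) and Nkx2-5 (-2.24, SE 0.50), which had under 1 CPM in every group mean, were lower. Mesenchymal genes gave 8 lower of 13, against 9 adjusted over the list alone (median -1.37, camera adjusted p = 1.31e-06, but adjusted p = 0.222 with an estimated correlation), with Snai2 (-5.34, SE 0.75), a repressor of epithelial genes, and Tgfb2 (-4.70, SE 0.36). Feeder fibroblast genes gave 1 higher and 13 lower of 23, also adjusted over the list alone (median -1.70, camera adjusted p = 2.5e-07, but adjusted p = 0.3 with an estimated correlation), and the collagen gene Col1a1 had 735 ± 218 and 28.5 ± 6.18 CPM. Trophectoderm genes gave 6 lower of 10, also adjusted over the list alone (median -1.34, camera adjusted p = 0.000838, but adjusted p = 0.222 with an estimated correlation), with Plac1 (-5.30, SE 0.65) and Cdx2 (-3.12, SE 0.61). Neural crest genes gave 2 higher and 6 lower of 11, also adjusted over the list alone (median -1.26, camera adjusted p = 0.0112, but adjusted p = 0.222 with an estimated correlation), with Ednrb (-5.62, SE 0.41). Targets of BMP and TGF-beta signalling gave 2 higher and 6 lower of 13, against 3 and 6 adjusted over the list alone (median -0.05, camera adjusted p = 0.0247, but adjusted p = 0.222 with an estimated correlation). Id2 (-3.36, SE 0.37) and Smad6 (-2.95, SE 0.36), both induced by BMP, were lower and the ligand gene Nodal (1.41, SE 0.22) was higher. The list median was -0.20, 0.01 and 0.00 without wild-type day 6 library 1, 2 or 3, and -0.09, -0.09 and -0.16 without Notch1-deficient day 6 library 1, 2 or 3. It was -0.10 under DESeq2 size factors, 0.05 with a replicate block and -0.50 with 2-exon names added, all called (camera adjusted p = 0.0255, 0.00387 and 0.0192). Smooth muscle genes gave 1 higher and 5 lower of 11, also adjusted over the list alone (median -0.48, camera adjusted p = 0.0253, but adjusted p = 0.3 with an estimated correlation). Over only the loci with under 50% of their exon length shared, the medians were -1.98 for cardiac progenitors, -1.93 for neural crest, -0.62 for BMP and TGF-beta targets and -1.48 for smooth muscle (camera adjusted p = 1.64e-06, 0.00247, 0.015 and 0.014).

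Lists of earlier stages, of the cell cycle and of epithelium were higher, none of them called with an estimated correlation. Primed epiblast genes gave 5 higher and 0 lower of 7, also adjusted over the list alone (median 1.43, camera adjusted p = 0.000229, but adjusted p = 0.152 with an estimated correlation), with Fgf5 (3.90, SE 0.54), the DNA methyltransferase gene Dnmt3b (2.64, SE 0.39) and the homeobox gene Otx2 (2.37, SE 0.48). Cell cycle genes gave 10 higher and 0 lower of 16, against 13 adjusted over the list alone (median 0.42, camera adjusted p = 7.6e-05, but adjusted p = 0.222 with an estimated correlation), with Ccne1 (1.94, SE 0.29) and Mcm2 (0.67, SE 0.12). Epithelial genes gave 6 higher and 1 lower of 12, against 6 and 2 adjusted over the list alone (median 0.57, camera adjusted p = 0.0152, but adjusted p = 0.3 with an estimated correlation), with Cdh1 (1.39, SE 0.16) and Epcam (1.29, SE 0.14); their median was 0.96 over only the loci with under 50% of their exon length shared (camera adjusted p = 0.000583). Primitive streak genes gave 6 higher and 2 lower of 10, against 7 and 2 adjusted over the list alone (median 1.63, camera adjusted p = 0.0215, but adjusted p = 0.227 with an estimated correlation), with Wnt3a (4.06, SE 0.51). Over only the loci with under 50% of their exon length shared, the streak list gave an adjusted p = 0.295 (camera). Naive pluripotency genes gave 4 higher and 0 lower of 17, against 5 adjusted over the list alone (median 0.53, camera adjusted p = 0.0435, but adjusted p = 0.331 with an estimated correlation), with Fgf4 (1.5, SE 0.22) and Dppa4 (1.19, SE 0.24). This call was lost without wild-type day 6 library 1 (camera adjusted p = 0.0594) or 2 (0.0531), Notch1-deficient day 0 library 1 (0.0558) or Notch1-deficient day 6 library 2 (0.109).

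Notch signalling genes went both ways at day 6. Of 16 Notch targets 2 were higher and 4 lower, also adjusted over the list alone (median -0.15, camera adjusted p = 0.296). Hey2 had 45.3 ± 11 CPM in the wild type and 2.64 ± 0.814 CPM in the deficient embryoid bodies. Besides Hey2 (-4.10, SE 0.40), Sox9 (-2.61, SE 0.47) and Heyl (-2.37, SE 0.38) were lower, and Lfng (1.45, SE 0.30), a glycosyltransferase that modifies Notch, was higher. Of 23 pathway components 3 were higher and 5 lower, also adjusted over the list alone (median -0.23, camera adjusted p = 0.31), with the ligand genes Dll1 higher (2.97, SE 0.60) and Dll4 lower (-2.49, SE 0.61). Hes1, a classical Notch target, had no usable counts, with 99.66% of its exon length shared with another locus. By deposited FPKM it had 46.7 in the wild type and 40.6 in the deficient embryoid bodies (log2 change -0.21 on FPKM + 1, adjusted p = 0.554, limma). Sarcomere genes gave 5 higher and 5 lower of 19, against 7 and 7 adjusted over the list alone (median -0.45, camera adjusted p = 0.816), with Myl7 higher (3.18, SE 0.44) and Tnni1 lower (-3.12, SE 0.46). Wnt targets were not called (4 higher and 3 lower of 14, also adjusted over the list alone, median 0.01, camera adjusted p = 0.981). Pmaip1 was higher (3.3, SE 0.21). The day 6 count of 6712 loci was 4283 without wild-type library 1 and 4395 without wild-type library 2. It was 11067 when only the 6 day 6 libraries were fitted.

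Genotype differences recurred across the days. There were 482 loci higher in Notch1-deficient cells on both days (119 if the calls were independent) and 534 lower on both days (197 if independent), while 33 and 131 were called in opposite directions. Of the day 0 calls, 45.2% returned in the same direction at day 6, and the changes had a Pearson correlation of 0.425 across genes. Hprt, Klhdc4, Ankrd31, Mirg, Uty, Eif2s3y, Ddx3y and Pmaip1 were among the loci called the same way on both days. The 1016 loci became 2082 without wild-type day 0 library 2, 636 without Notch1-deficient day 0 library 2 and 617 without both day 0 libraries numbered 3.

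The fifth comparison asked which changes over differentiation depended on genotype, as the change in Notch1-deficient cells minus that in the wild type. Genes of yolk sac endoderm, vessels and imprinted regions rose less or fell in the deficient cells, and neural genes rose more or fell less. This interaction was called for 2668 loci, 1494 positive and 1174 negative (edgeR's quasi-likelihood test, adjusted p under 0.05). Positive ones were 56% of the calls, 48.2% under DESeq2 size factors and 57.4% under upper quartile scaling. The count was 1592 without wild-type day 6 library 1, 1411 without wild-type day 6 library 2 and 1753 without Notch1-deficient day 6 library 3, and 1458 without both day 0 libraries numbered 3. Notch1 was not called (0.71, SE 0.40; 0.26 without wild-type day 0 library 1, 0.13 on FPKM + 1 and 0.01 on FPKM + 0.1). Positive interactions included Wnt8a (6.51, SE 0.56), Slc27a2 (5.74, SE 0.75) and Dll1 (5.20, SE 0.83). Negative ones included H19 (-8.83, SE 0.96), Igfbp5 (-6.97, SE 0.78), Dlk1 (-6.55, SE 0.79) and Tbx20 (-6.34, SE 0.68). The H19 value rests in part on Notch1-deficient day 0 libraries in which H19 rose with the feeder list. Of 23 extraembryonic endoderm genes 15 had a called negative interaction and 0 a positive one, against 17 adjusted over the list alone (median -2.01, and -2.66 with genes absent from a group set at their bound of 3 counts; camera adjusted p = 1.41e-18, and adjusted p = 0.00742 with an estimated correlation). Of 20 imprinted genes 12 were negative, against 13 adjusted over the list alone (median -1.89, camera adjusted p = 2.33e-17, and adjusted p = 0.00365 with an estimated correlation). Of 21 endothelial and blood genes 10 were negative, also adjusted over the list alone (median -2.28, camera adjusted p = 9e-17, and adjusted p = 0.0193 with an estimated correlation). Of 13 neuroectoderm genes 5 were positive and 1 negative, against 6 and 1 adjusted over the list alone (median 1.84, camera adjusted p = 0.000857, and adjusted p = 0.0497 with an estimated correlation). These 13 were the tested part of 26 listed genes. By day, the neuroectoderm list was called in neither genotype. Its median was -0.20 in the wild type and 0.83 in Notch1-deficient cells (camera adjusted p = 0.0617 and 0.702).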

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

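The tests of the feeder list's correlation, of the region around Notch1 and of other splits of the samples were chosen before the data were examined; the tests of splits by day for the interaction, of splits that part the day 0 pairs over both days, of a return of day 0 calls at day 6, of stem cell expression, of mislabelling, of line history, of scaling, of feeder RNA carried over to day 6 over all list members and of slower differentiation were chosen after.

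What made the following results stand out is a difference between the genotypes in the change over differentiation, tested as an interaction with edgeR's quasi-likelihood test for genes and camera for lists. Of all loci, 2668 passed. Of 100 splits by genotype drawn from the 200 possible, 4 gave as many loci, the real one included. Of the 46 that parted all 3 pairs of same-numbered libraries at day 0, 2 gave as many, so both shares lie little under the 5% bound. Most splits mixed the genotypes within day 6, which turned the day 6 genotype difference into spread within groups. Such splits gave few or no calls and could hardly reach 2668, so neither share can exclude chance. The highest other value, 6920, came from the split that exchanged the genotypes at day 6 only and so points to the structure of the samples. For the 13 lists called, 14 of 100 splits gave as many and the highest other was 17, so chance cannot be excluded for that count. When the days were exchanged instead, 4 of 100 splits gave as many loci and the highest other was 12378, from the split that exchanged the days in Notch1-deficient cells only, which again points to the structure of the samples; for lists, 12 of 100 gave as many and the highest other was 16. List medians of the interaction were -2.01 for extraembryonic endoderm, -2.28 for endothelium and blood, -1.89 for imprinted genes, -3.54 for the sex chromosome list and 1.84 for neuroectoderm. These 5 kept their call with an estimated correlation. The sex chromosome value rests on Y-linked counts in Notch1-deficient day 0 libraries 1, 2 and 3, which rose with the feeder markers (Eif2s3y 2.69, 7.56 and 13.6 CPM against a feeder mean log2 CPM of 4.33, 5.39 and 5.99), so feeder RNA lost by day 6 may explain it; with 3 libraries this was not tested. The medians were -1.50 for cardiac progenitors, -1.43 for neural crest, -1.87 for trophectoderm, -1.23 for feeder fibroblast genes, -1.33 for BMP and TGF-beta targets, -1.23 for mesenchymal genes, 1.77 for primed epiblast and 0.58 for cell cycle genes. These 8 lost their call with an estimated correlation (adjusted p = 0.0637, 0.111, 0.111, 0.368, 0.0807, 0.302, 0.146 and 0.302, in this order, camera). The feeder fibroblast median was -0.80 without wild-type day 0 library 2, and the median of BMP and TGF-beta targets was -0.77 without Notch1-deficient day 0 library 3.

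Among genes, interactions were positive for Wnt8a (6.51), Slc27a2 (5.74), Dll1 (5.20), the metalloproteinase Mmp25 (4.47), Miat (4.43), the peptide hormone gene Apln (4.28), the endocytic receptor gene Lrp2 (4.08), the channel gene Trpm1 (3.98), Map2 (2.56), Stmn2 (1.90) and Nodal (1.79). They were negative for H19 (-8.83), Eif2s3y (-6.99), Igfbp5 (-6.97), Adam12 (-6.66), Dlk1 (-6.55), Postn (-6.42), Ddx3y (-6.35), Dnaaf1 (-6.35), Tbx20 (-6.34), Cdh5 (-6.30), Ednrb (-6.16), Erg (-5.27), Id2 (-4.94), Plac1 (-4.92), Apob (-4.43), Hey2 (-3.73), Tgfb2 (-3.56) and Bmp2 (-3.47). The H19, Eif2s3y and Ddx3y values rest in part on Notch1-deficient day 0 levels that rose with the feeder markers. The Trpm1 call was lost without wild-type day 0 library 1 (value 2.52, adjusted p = 0.0686), wild-type day 6 library 1 (0.0819) or 2 (0.0826), Notch1-deficient day 0 library 3 (0.0701) or Notch1-deficient day 6 library 2 (0.0745) or 3 (0.05), edgeR's quasi-likelihood test, and adjusted p ranged up to 0.111 over its alternatives.

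The first pattern is the high level of fibroblast genes at day 0. Within groups the 23 members of the feeder list deviated together, with a mean correlation of 0.783 over the 6 day 0 libraries, against a median of 0.007 in 1000 random gene sets, of which 0 were as high; feeder cells, which the labels name as a culture option, may therefore have contributed RNA, with Col1a1 at 504 and Lox at 217 CPM in the wild type. They were not the whole of the day 0 genotype calls, since 45.2% of these returned in the same direction at day 6, against 14.1% for independent calls. How far feeder RNA lost by day 6 accounts for the loci that fell in either genotype was not tested. Expression by the stem cells themselves stays open, because all 23 members had at least 1 CPM in the wild type at day 0, and 20 of them still at day 6, and bulk RNA does not say which cell made them.

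The second pattern is the set of 1016 loci that differed in the same direction on both days. Of 100 splits only the real one gave as many, the highest other giving 664 (164 among the 46 that parted all 3 same-numbered pairs at day 0). Splits that mixed the genotypes within day 6 all gave 0, because the genotype difference then became spread within groups. They could not reach 1016, so these splits cannot exclude chance. A mislabelled library is argued against by Notch1, which put 0 libraries on the other genotype's side. Sequence around the targeted gene is argued against as the main source, since 0.492% of the 1016 loci (5) lay within 5 Mb of Notch1, where 0.829% of tested loci lie (Fisher's exact test, 2-sided p = 0.288). A separate history of the lines stays open, since genotype and line cannot be told apart for these 1016 loci. The same holds for every other genotype and interaction result here. Hprt (14.6 and 284 CPM at day 0), the loss of Y-linked transcripts and Mirg are candidates for such differences that might have nothing to do with Notch1. At day 6 Hprt had 1.39 ± 0.0907 CPM in wild-type and 232 ± 12.1 CPM in deficient libraries, and Uty 48.1 ± 0.981 and 0.0209 ± 0.0225 CPM.

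The third pattern is the lower level of extraembryonic endoderm, endothelial and imprinted genes in Notch1-deficient embryoid bodies. The 51 members called lower had a median of -3.59. That choice of members fixes the sign and enlarges the size. The list medians over all tested members, given above, are smaller in size. Scaling is argued against, since a factor shared by all loci of a library cannot set a list apart from the other loci, as these 3 lists were with all their tested members (highest adjusted p = 0.0287, camera with an estimated correlation). Feeder RNA carried into wild-type embryoid bodies is argued against, since 89.1% of all 64 tested members (57) were higher at day 6 than at day 0 in the wild type. This largely restates the rises of these lists in the wild type reported above and is no separate test. Slower differentiation of the deficient cells is consistent with higher epiblast and streak genes, lists called with the preset correlation only, but stays open, since with a single harvest day a delay and another course cannot be told apart; 366 loci changed in opposite directions by day in the genotypes. A need for Notch1 in forming these tissues, and a difference between the lines, stay open as well and were not tested.

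For the other counts from 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real and highest other counts of loci were 10314 and 0 for differentiation in the wild type, 8561 and 0 in Notch1-deficient cells, and 6712 and 0 for the genotype at day 6 (1 split as high in each, the real one). For lists they were 12 and 14 (2 splits as high), 8 and 12 (6 splits) and 17 and 16 (1 split). For the genotype at day 0 the real and highest other counts were 2246 and 3543 (2 splits as high). The higher count came from the split that keeps the libraries numbered 1 together, and those numbered 2, and parts only those numbered 3; the 3 other splits that part all 3 pairs gave at most 0, both without a block and with a replicate block, under which the real count was 3360. Lists at day 0 gave 2 and 7 (9 splits as high). For the 5047 loci called the same way by day in both genotypes, 1 of 100 splits gave as many. The highest other was 366, from the split that exchanged the days in Notch1-deficient cells only. All drawn splits that mixed the days within a genotype gave 0, because the day difference then became spread within groups. These splits therefore cannot exclude chance.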

How the results depend on the processing

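The alternatives named here as added were chosen after seeing the data: both day 0 libraries numbered 3 left out, loci with under 50% of exon length shared, 2-exon names, and the feeder covariate. Notch1 kept its direction and call under every alternative run, from -3.54 to -2.85 at day 0 and -2.75 to -2.48 at day 6 when 1 library was left out, and from -3.49 to -2.07 and -3.35 to -1.94 under the others. Of 195 called values of named genes, 8 lost their call or changed direction under any alternative, 2 when 1 library was left out and 7 with FPKM. Igf2 was reversed with FPKM, at -4.22 (FPKM + 1, with and without filter) and -7.47 (FPKM + 0.1) for differentiation in the wild type, and 4.92 (with and without filter) and 8.2 for the genotype at day 6; FPKM listed at 0 in wild-type embryoid bodies shows the cause. The others were Prg4 and AI506816 at day 0, Miat and Ddx3y in the interaction, Trpm1, and Jag1 at day 0. Miat had an adjusted p = 0.0844 unfiltered (limma). Ddx3y had 0.226 and, unfiltered, 0.307 on FPKM + 1, but 0.0111 on FPKM + 0.1 (adjusted p, limma). Jag1 had 0.0865 without both libraries numbered 3 and 0.162 with only the 2 groups (adjusted p, edgeR). With the feeder covariate added to that fit of the 2 groups, Jag1 had 0.244 (adjusted p, edgeR).

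Counts of loci moved by more than 1.5 times as follows, and the cause was not tested except that fewer loci or libraries entered some fits. A mean CPM of at least 1 gave 6195 and 5183 for differentiation in the wild type and in Notch1-deficient cells, 1133 and 4295 for the genotype at day 0 and day 6, and 486 shared genotype calls. FPKM + 1 gave 6130, 4879, 846 and 4334 for the 4 contrasts, FPKM + 0.1 gave 6181, 5036, 926 and 4408 and 1742 for the interaction, and unfiltered FPKM gave 1441 at day 0. DESeq2 gave 3714 at day 0 and 4099 for the interaction. Fits of only the 2 groups gave 687 at day 0 and 11067 at day 6. Without both day 0 libraries numbered 3, the counts were 962 at day 0, 1458 for the interaction and 617 shared calls. The feeder covariate, fitted on only the day 0 libraries, gave 449 at day 0, against 687 for those libraries without it. Without 1 library, counts ran from 1095 to 5964 at day 0, 4283 to 7980 at day 6, 1411 to 3943 for the interaction and 636 to 2082 for shared calls, while differentiation ran from 7868 to 11570 in the wild type and 6320 to 9964 in Notch1-deficient cells.

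With an estimated correlation the lists called fell from 12 to 5 and from 8 to 0 for differentiation in the wild type and Notch1-deficient cells, from 2 to 0 and from 17 to 5 for the genotype at day 0 and day 6, and from 13 to 5 for the interaction; 15 of 52 calls were kept. The test fry, which does not compare a list with other genes, called 19 and 13 lists for differentiation and lost 3 list calls. At day 0 the lists called were 1 without both libraries numbered 3, 1 with loci under 50% shared (too few sex chromosome genes remained), and 1 to 4 without 1 library. The 2-exon names changed 0 of 52 list calls. Across genes, the correlation of genotype changes was 0.342 without a filter, 0.37 at a mean CPM of at least 1, and 0.383 to 0.422 without 1 library; that of differentiation changes was 0.521 without a filter and 0.567 to 0.637 without 1 library.

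With the library number as a replicate block, counts of called loci were 3360 for the genotype at day 0, 11029 for differentiation in the wild type and 9412 in Notch1-deficient cells. The block ended 1 list call, naive pluripotency at day 6 (camera adjusted p = 0.0508), and changed no call of a named gene; in the day 6 and differentiation contrasts not every library correlated best with its own number. Depth limits little here, since the spread between libraries exceeded counting error, but 3 libraries per group leave changes near 2-fold mostly uncalled.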

Other observations

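Several regulators of the early embryo could be read only by FPKM, since their exons are shared with neighbouring loci, and were looked at after the data had been seen. In day 6 embryoid bodies the mesoderm factor T had 17.1 ± 9.5 FPKM in the wild type and 126 ± 61.1 in Notch1-deficient libraries (2.79 on log2(FPKM + 1), adjusted p = 0.00105, limma). Eomes (13.4 and 91.0 FPKM, adjusted p = 0.000823), Lhx1 (3.59 and 75, 2.44e-05) and Gsc (1.55 and 15, 3.53e-05), all factors of the streak and organiser, were higher as well, by limma, while the streak gene Evx1 (0.65, adjusted p = 0.284) and Dkk1 (-0.45, adjusted p = 0.137) were not called. The pluripotency factor gene Nanog had 52.9 and 129 FPKM (1.27, adjusted p = 0.00326, limma), and the neural factor gene Zic2 7.44 and 47.7 FPKM (2.55, adjusted p = 0.002, limma). Of other neural genes Pax6 was not called (0.07, adjusted p = 0.914, limma) and Irx3 was lower (-0.80, adjusted p = 0.00501, limma). Bmp4 had 63.9 and 16.2 FPKM (-2.14, adjusted p = 0.014, limma) and Hoxb6 13.5 and 0.26 FPKM (-3.49, adjusted p = 1.1e-05, limma). The imprinted Mest had 578 and 63.6 FPKM, and Airn, an imprinted noncoding RNA, 11.4 and 0.286 FPKM. Of other imprinted genes Nnat (0.57, adjusted p = 0.0872, limma) and Nespas (0.38, adjusted p = 0.112, limma) were not called.

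By class, 3632 of 11849 tested protein-coding loci, 317 of 998 annotated noncoding loci and 1700 of 7160 unannotated intergenic loci differed by genotype at day 6 (edgeR's quasi-likelihood test). At day 0 these counts were 980, 106 and 810. Among loci with a mean log2 CPM of at least 2, genotype medians per autosome lay between -0.03 and 0.102 over both days, while the 3 Y loci had medians of -3.86 at day 0 and -10.85 at day 6. Eif2s3y varied from 2.69 to 7.56 and 13.6 CPM among Notch1-deficient day 0 libraries 1, 2 and 3, and had at most 0.0859 CPM at day 6. Of 872 tested X loci, 30 differed in the same direction on both days, 15 of them higher in Notch1-deficient cells.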
